A study of Homo sapiens with 9 samples.

How the data were processed

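RNA from Huh7, a human hepatocarcinoma cell line, was measured on 9 Affymetrix arrays of a single whole-transcriptome design with 1 colour and biotin label. The arrays fell into 3 groups of 3, which the labels give as biological replicates: scramble siRNA, siRNA against the subunits of serine palmitoyltransferase (called SPTLC123 in the labels) and siRNA against DEGS1. Per the labels, siRNA was used at a final 20 nM with a lipid reagent. The labels place the samples 72 h after transfection, whereas the treatment protocol adds a reduced-serum conditioned medium at 72 h and harvests the cells after another 24 h. Which of these statements holds stayed open.

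The deposited values are normalized probe-set intensity on a linear scale, 1 per probe set and array. Per the submitters' processing notes the tools were RMA, GCRMA 2.12.1 and limma 2.14.7, with no role or order given, so whether RMA or GCRMA made the values stayed open. The table held 54675 probe sets, 62 of them Affymetrix controls, with values from 4.88 to 27330.6 and array medians from 27.92 to 30, so the values were read as already normalized between arrays. Array data have no read depth; the number of arrays and the signal over background limit the precision, and many probe sets lay near background, where a fold change is compressed.

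Values were log2-transformed with no pseudocount, since none was at or below 0. Of the 54613 probe sets without controls, 41091 had 1 gene symbol in the platform's annotation table, 1801 had several and 11721 were not listed there. Each of the 19775 genes was represented by the 1-gene probe set with the highest mean over all 9 arrays, and 10523 genes had more than 1 such probe set. Of the 1-gene probe sets, 41037 matched the RefSeq gene table by gene number, and no symbol changed. The third targeted subunit was not analysed here.

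A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, statmod 1.5.0 for the robust alternative). This left 6 residual degrees of freedom. The 3 comparisons were SPTLC123 against scramble, DEGS1 against scramble and DEGS1 against SPTLC123. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all genes; a gene was called at an adjusted p under 0.05, and a further count asked for a log2 change of at least 1. An F test over both contrasts against scramble gave the genes differing among the 3 groups. Values after ± are the SE of the moderated limma fit for log2 changes and the SD over 3 arrays for levels.

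A set of 22 gene lists, fixed before the data were examined and free of the siRNA targets, was tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. The same test with an estimated correlation and fry stood beside it. Between 14 and 31 members of each list were measured. The genes named were chosen by a rule written at the same time: the targeted genes; the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap and whose higher group lay above the median of all probe sets (5 and 5 for DEGS1 against SPTLC123); up to 4 members of each list by adjusted p; and the 5 genes called in both comparisons against scramble in the same and in opposite directions with the largest smaller change.

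The comparisons against scramble share their 3 control arrays. Unchanged groups sharing these controls were simulated 100 times from the fitted spread, with each gene drawn independently. The covariance and overlap in them were set beside the observed ones. With 3 control arrays, a split that leaves 2 in each part was not possible.

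The fit was tested on simulated data with 200 changed genes among 19775. For SPTLC123 against scramble it recovered 47.8% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, with 6.82% of the calls not among the changed genes. For DEGS1 against scramble these values were 41.8%, 95.5%, 100% and 2.47%, and for DEGS1 against SPTLC123 41.8%, 97.0%, 100% and 4.79%. Each gene was drawn independently, with the same spread in all arrays. Differences between arrays that many genes share were not simulated, so these rates need not hold for the real arrays.

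Alternative settings fixed beforehand were every probe set on its own, the mean of a gene's probe sets, a filter on dim genes, quantile normalization, median centring, a variance trend with robust eBayes, fits on only the 2 groups compared, array weights, an adjusted p threshold of 0.01, the replicate number as a block, and leaving out each array. After the data had been seen, 2 alternatives were added because the 3' and 5' control probe sets set 3 arrays apart: the actin 3' minus 5' difference of each array as a covariate, and a fit without these 3 arrays. In the latter, DEGS1 has 1 array, which is assumed to vary like the other groups. A comparison of DEGS1 with SPTLC123 within the 3 arrays and a test of a list without its aldo-keto reductase genes were also added then.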

Results

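Gene expression was measured in Huh7 hepatocarcinoma cells after silencing of enzymes of de novo ceramide synthesis. Serine palmitoyltransferase, made of the SPTLC subunits, condenses serine with palmitoyl-CoA in the first step of the pathway, and DEGS1, dihydroceramide desaturase, turns dihydroceramide into ceramide in the last. The design asks which genes respond to silencing at the entry of the pathway, which respond to silencing at its end, and where the responses differ. Enzyme activity and ceramide levels were not analysed here. Each of the 3 groups (scramble, SPTLC123 and DEGS1 siRNA) held 3 arrays, which limits the precision, and 19775 genes were tested.

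Both knockdowns were seen in every array of the labelled group. SPTLC1 fell from 10.94 ± 0.10 in scramble to 8.67 ± 0.12 in SPTLC123 on the log2 intensity scale, a change of -2.27 ± 0.11 that left 20.7% of the signal. SPTLC2 changed by -1.05 ± 0.11, with 48.4% of the signal left. Of its 4 other probe sets 1 was also called lower, and 84.5% and 104% of the signal was left in another pair. DEGS1 fell from 8.73 ± 0.13 in scramble to 5.00 ± 0.19 in DEGS1 siRNA, with 7.55% of the signal left, and its second probe set changed by -3.23. The adjusted p of these changes in limma with Benjamini-Hochberg adjustment were 1.42e-06, 0.00024 and 7.32e-07. In the probe sets used, neither siRNA changed the targets of the other at the threshold. DEGS1 differed by -0.12 ± 0.16 in SPTLC123 (adjusted p = 0.731). SPTLC1 and SPTLC2 differed by -0.23 ± 0.11 (adjusted p = 0.253) and 0.19 ± 0.11 (adjusted p = 0.343) in DEGS1 siRNA. Another SPTLC1 probe set changed by -0.52 in DEGS1 siRNA in a limma fit over every probe set (adjusted p = 0.0225).

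**Figure D1:**
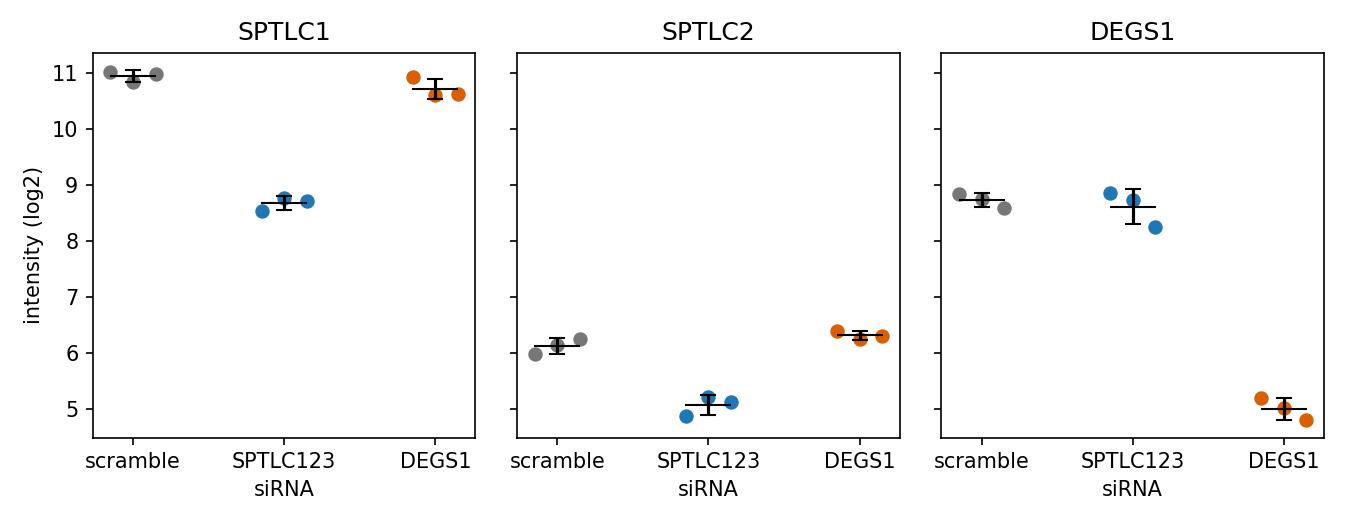
Log2 intensity of SPTLC1, SPTLC2 and DEGS1 in each array (points), with the mean and SD of the 3 arrays of each siRNA group (bars). SPTLC1 lies at 8.67 ± 0.12 in SPTLC123 against 10.94 ± 0.10 in scramble, and DEGS1 at 5.00 ± 0.19 in DEGS1 siRNA against 8.73 ± 0.13 in scramble.

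The arrays differed in the 5' signal of control transcripts. The 3' minus 5' log2 difference of the actin control probe sets lay between 0.40 and 0.56 in 6 arrays, but at 1.15 in SPTLC123 replicate 3, 1.31 in DEGS1 replicate 2 and 1.25 in DEGS1 replicate 3. The GAPDH controls split the arrays alike, from -0.09 to 0.01 in the 6 arrays and from 0.25 to 0.40 in the other 3. No scramble array was among these 3 arrays with weak 5' signal, so counts without them, and the named genes and lists whose calls ended without them, are given with each comparison. The first principal component, with 39.5% of the variance, put these 3 arrays highest, and the second, with 28.7%, separated SPTLC123 from the other groups.

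**Figure D2:**
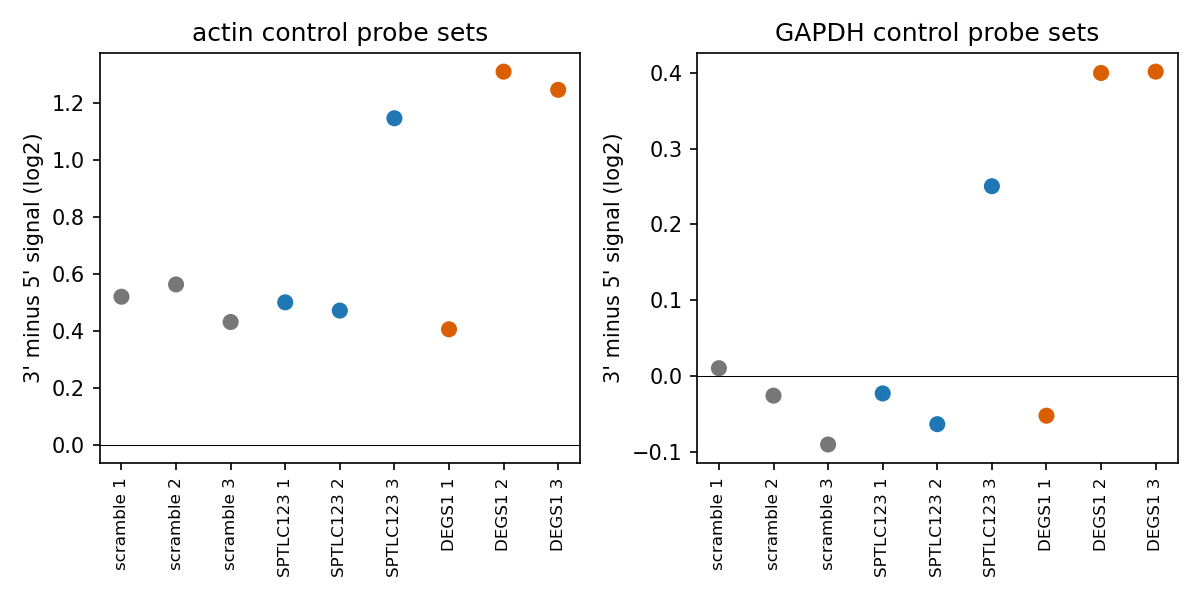
Difference between 3' and 5' control probe sets of actin and GAPDH (log2) for each of the 9 arrays, coloured by siRNA group. SPTLC123 replicate 3 and DEGS1 replicates 2 and 3 lie above the other 6 arrays in each panel, for actin at 1.15, 1.31 and 1.25 against at most 0.56.

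The comparison of SPTLC123 siRNA with scramble asks what follows silencing at the entry of the pathway. IGFBP3, which binds insulin-like growth factors, rose by 3.40 ± 0.16 (adjusted p = 8.99e-07), and SI, the intestinal sucrase-isomaltase, by 3.13 ± 0.10 (adjusted p = 1.11e-07). TDO2, the tryptophan dioxygenase of the liver, rose by 2.29 ± 0.32, though its other probe set had the opposite sign, and MET, the receptor of hepatocyte growth factor, by 2.01 ± 0.09. SERPINA7, which carries thyroid hormone in plasma, rose from 3.78 ± 0.06 to 5.91 ± 0.50. LZTFL1 (2.28), the mitochondrial phosphatase PTPMT1 (2.06), GPRC5B (1.99), the metallothionein MT1M (1.98) and the protocadherin PCDH7 (1.95) completed the 10 largest increases. The largest decreases were NHLRC3 at -3.04 ± 0.19 and CPOX, an enzyme of haem synthesis, at -2.93 ± 0.19. Of the 2 other probe sets of NHLRC3, 1 had the same sign and 0 were called. PLOD2, a lysyl hydroxylase of collagen, changed by -2.45 ± 0.15, DONSON, a replication factor, by -2.30 ± 0.11, and NNMT, which methylates nicotinamide, by -2.28 ± 0.52. FAM98B (-2.36), the peptide hormone SPX (-2.31), TMT1A (-2.13) and the hydroxy-carboxylic acid receptor HCAR3 (-2.13) stood with SPTLC1 itself among the 10. The scramble level of SI, TDO2, SERPINA7 and MT1M and the SPTLC123 level of NHLRC3 lay below the median of all probe sets (4.87), so the size of these changes is uncertain. All 20 were called by limma with Benjamini-Hochberg adjustment, but NNMT lost its call without SPTLC123 replicate 3 (adjusted p = 0.0643).

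In all, 1966 genes were called in SPTLC123 against scramble, 1051 higher and 915 lower, of which 271 changed at least 2-fold (116 higher and 155 lower). Leaving out SPTLC123 replicate 1 gave 1178 genes. Without the 3 arrays with weak 5' signal 1502 genes were called, 1290 of them among the 1966. Of 89 named and called genes 22 lost the call then, with a median of 92.1% of their log2 change left. NNMT, ASNS, BNIP3L, DHCR7 and SMPD1 were among these (adjusted p from 0.0513 to 0.0929). With median centring 65.3% of the calls were higher, against 53.5%, and with quantile normalization 46.5%.

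Of 25 measured genes of sphingolipid synthesis, 3 rose and 2 fell (3 and 2 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.901). CERS2, the ceramide synthase for very long acyl chains, changed by -1.53 ± 0.13 (adjusted p = 4.66e-05) and GLTP, a glycolipid transfer protein, by -1.13 ± 0.10 (adjusted p = 6.79e-05). UGT8, which adds galactose to ceramide, rose by 1.14 ± 0.13 (adjusted p = 0.000302). Of 27 genes of sphingolipid breakdown and sphingosine 1-phosphate, 1 rose and 5 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.140). SGPL1, the lyase that ends sphingolipid breakdown, changed by -0.76 ± 0.09 and the acid sphingomyelinase SMPD1 by 0.40 ± 0.09. Among 24 genes of glycerophospholipid synthesis 4 rose and none fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.089), with CDS1, which makes CDP-diacylglycerol, up by 1.90 ± 0.15.

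At the preset correlation camera called 5 of the 22 lists after SPTLC123 siRNA, and 0 with an estimated correlation. Of 24 genes of lipoproteins and cholesterol efflux none rose and 5 fell (0 and 7 adjusted over the list alone; camera Down, adjusted p = 0.00283; adjusted p = 0.323 with an estimated correlation). APOC3 changed by -1.28 ± 0.14, APOM, the sphingosine 1-phosphate carrier of plasma, by -1.31 ± 0.19, the sterol acyltransferase SOAT2 by -1.02 ± 0.12 and NR1H3, the liver X receptor alpha, by -0.99 ± 0.16. In the hepatocyte identity list 1 of 27 genes rose and 8 fell (2 and 11 adjusted over the list alone; camera Down, adjusted p = 0.00364; adjusted p = 0.323 with an estimated correlation). The plasma proteins HP (-1.12), TTR (-1.03) and HPX (-0.88) were among those that fell. The ATF4 and integrated stress response list had no called increase and 4 decreases of 24 (1 and 12 adjusted over the list alone; camera Down, adjusted p = 0.00287; adjusted p = 0.646 with an estimated correlation). The endoplasmic reticulum oxidase ERO1A changed by -1.17 ± 0.09 and the asparagine synthetase ASNS by -1.30 ± 0.33. Of 20 hypoxia genes none rose and 5 fell (0 and 7 adjusted over the list alone; camera Down, adjusted p = 0.00202; adjusted p = 0.492 with an estimated correlation). The prolyl hydroxylase subunit P4HA1 changed by -1.16 ± 0.21, though its other probe set had the opposite sign, and BNIP3L by -1.28 ± 0.27. In the oxidative stress and NRF2 list 1 of 21 genes passed, AKR1B10, which rose by 1.50 ± 0.26 (3 higher and 0 lower adjusted over the list alone; camera Up, adjusted p = 0.00919; adjusted p = 0.492 with an estimated correlation). The last list was not called with dim genes left out (adjusted p = 0.131). By fry, which asks whether a list moves one way on balance, the ATF4, hypoxia and NRF2 lists were not called (adjusted p = 0.183, 0.0813 and 0.0827). Fry did call 3 lists that camera did not: sphingolipid breakdown (Down, adjusted p = 0.0165), interferon response (Down, adjusted p = 0.0165) and glycerophospholipid synthesis (Up, adjusted p = 0.0174). All 5 lists were called without the 3 arrays with weak 5' signal.

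Other lists were not called by camera in SPTLC123 against scramble, though single members were called. SOD2, the mitochondrial superoxide dismutase, changed by -1.99 ± 0.15 within the inflammation and NF-kappaB list (2 higher and 1 lower of 23; adjusted over the list alone 2 and 3). PMAIP1 changed by -1.85 ± 0.24 within the p53 targets and apoptosis list (3 higher and 3 lower of 20; 5 and 3 adjusted over the list alone). IFIT1 changed by -1.52 ± 0.21 within the interferon response list (0 higher and 3 lower of 25, and 0 and 4 adjusted over the list alone). The SPTLC123 level of IFIT1, 3.70, lay below the median of all probe sets (4.87), so the size of this change is uncertain. CCNE1, cyclin E1, rose by 1.13 ± 0.13 in the cell cycle list, though its other probe set had the opposite sign. In this list 3 were higher and 1 lower of 31 (5 and 1 adjusted over the list alone). CPT1A, the gatekeeper of mitochondrial fatty acid oxidation, rose by 0.88 ± 0.10 as the only call among 24 genes of fatty acid oxidation and PPAR-alpha targets (1 and 0 adjusted over the list alone). EDEM1 changed by -1.11 ± 0.12 and PDIA4 by 0.70 ± 0.09 in the unfolded protein response list (2 higher and 1 lower of 20; 2 and 1 adjusted over the list alone). ACSL5 changed by -0.91 ± 0.15 among fatty acid and triglyceride synthesis genes (4 higher and 2 lower of 25; 4 and 3 adjusted over the list alone). MGLL changed by -0.71 ± 0.10 among lipid droplet and lipolysis genes (1 higher and 1 lower of 19; 1 and 2 adjusted over the list alone). DHCR7 rose by 0.44 ± 0.12 as the only call among 19 genes of cholesterol synthesis and uptake (0 and 0 adjusted over the list alone). By camera this list was called Up without scramble replicate 2 (adjusted p = 0.00498) and with array weights (adjusted p = 0.0128). Over all arrays its adjusted p was 0.646 with an estimated correlation. The lysosomal protease CTSB changed by -0.72 ± 0.08 in the autophagy and lysosome list (0 higher and 2 lower of 24; 4 and 3 adjusted over the list alone). CDH1 changed by -0.80 ± 0.12 among actin cytoskeleton, adhesion and matrix genes (1 higher and 3 lower of 26; 1 and 4 adjusted over the list alone). FOXO3 changed by -0.48 ± 0.10 among insulin signalling and glucose metabolism genes (1 higher and 4 lower of 22; 2 and 7 adjusted over the list alone). KRT19 rose by 0.75 ± 0.16 among markers of other liver cell types, though its other probe set had the opposite sign. Of these markers 2 were higher and 1 lower of 23 (2 and 1 adjusted over the list alone). None of the 14 reference genes was called, over all genes or over the list alone.

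The comparison of DEGS1 siRNA with scramble asks the same for the last step. SI rose by 3.07 ± 0.10 (adjusted p = 1.38e-07), VCAN, the matrix proteoglycan versican, by 2.18 ± 0.19 (adjusted p = 8.32e-05) and MET by 1.81 ± 0.09 (adjusted p = 3.78e-06). LZTFL1 (2.02), the transcription factor RFX6 (1.96), the netrin NTN4 (1.92), PCDH7 (1.80), FAM78B (1.71), PTPMT1 (1.60) and the Wnt receptor FZD5 (1.59) were the other large increases. After DEGS1 itself, ARG1, the arginase of the urea cycle, changed by -3.27 ± 0.45 and SLC44A1, a choline transporter, by -2.64 ± 0.14, with 1 of its 5 other probe sets called the opposite way. AKR1B10, an aldo-keto reductase, changed by -2.28 ± 0.26, the deubiquitinase USP46 by -2.22 ± 0.20, the cytokine TNFSF4 by -2.09 ± 0.16 and the calcium sensor VSNL1 by -2.07 ± 0.23. SPX (-2.53), S100P (-2.40) and HCAR3 (-2.04) completed the 10. The scramble level of SI and NTN4 and the DEGS1 level of AKR1B10 lay below the median of all probe sets (4.87). All 20 passed limma with Benjamini-Hochberg adjustment and with the actin 3'/5' covariate. With DEGS1 replicate 1 as the only DEGS1 array, RFX6 differed by 1.74 (adjusted p = 0.0883), ARG1 by -2.58 (adjusted p = 0.0761), SPX by -2.36 (adjusted p = 0.109) and S100P by -2.30 (adjusted p = 0.101). HCAR3 kept its call then, at -1.23 (adjusted p = 0.0202), and stood at -1.35 with the covariate.

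In all, 1918 genes were called in DEGS1 against scramble, 922 higher and 996 lower, of which 226 changed at least 2-fold (84 higher and 142 lower). This count moved with the arrays of weak 5' signal: 1114 genes were called with the actin 3'/5' covariate, 977 of them among the 1918, and 259 without the 3 arrays, 244 of them among the 1918. The balance turned without the 3 arrays, with 149 higher and 110 lower, and with the covariate, with 592 higher and 522 lower. Leaving out scramble or DEGS1 replicate 2 or 3, or keeping every probe set, gave 50.9% to 53.4% higher, against 48.1%, and a fit on the 2 groups compared left it about even. Leaving out single arrays gave 3614 genes without DEGS1 replicate 1, 841 without replicate 2 and 801 without replicate 3, and 1140 and 960 without scramble replicates 2 and 3. At least 2-fold, 495 changed without DEGS1 replicate 1 and 119 without the 3 arrays (65 higher and 54 lower). Of 96 named and called genes 64 lost the call without the 3 arrays, where 1 DEGS1 array is left, with a median of 78.5% of their log2 change left. Besides the 4 above, AKR1C1, ASNS, CCNE1, CXCL3, HPRT1, IGFBP3, LSS, NDRG1, NQO1, PDK1, PMAIP1, SLC3A2, SLC7A11, SOAT1, TFRC and UGCG were among these (adjusted p from 0.0636 to 0.552). LSS stood at 0.58 then, NQO1 at -0.37, NDRG1 at 0.35 and PDK1 at -0.56.

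The ATF4 and integrated stress response list was lower after DEGS1 siRNA, with no increase and 10 decreases among 24 genes (1 and 14 adjusted over the list alone). Its camera adjusted p was 2.36e-06, and adjusted p = 0.401 with an estimated correlation. MTHFD2, of mitochondrial folate metabolism, changed by -1.56 ± 0.16, ASNS by -1.79 ± 0.33, the cystine transporter SLC7A11 by -1.25 ± 0.24 and its partner SLC3A2 by -0.73 ± 0.09. In the oxidative stress and NRF2 list 7 of 21 genes fell and none rose (7 and 0 adjusted over the list alone; camera Down, adjusted p = 0.00056; adjusted p = 0.401 with an estimated correlation). AKR1C1 changed by -1.86 ± 0.23, AKR1C2 by -1.56 ± 0.18 and the quinone reductase NQO1 by -0.65 ± 0.13. Probe sets of the AKR1C genes can share signal between these close paralogs. Both lists were called without the 3 arrays with weak 5' signal, where 2 members of each were called. The hepatocyte identity list had 1 increase, FOXA1 at 0.75 ± 0.12, and 5 decreases among 27 (1 and 6 adjusted over the list alone; camera Down, adjusted p = 0.0438; adjusted p = 0.401 with an estimated correlation). HP changed by -1.02 ± 0.14 and HPX by -0.98 ± 0.12. Leaving out scramble replicate 1 or DEGS1 replicate 1 gave adjusted p = 0.112 and 0.143, and 4 other settings gave 0.0506 to 0.137. Of 20 hypoxia genes 1 rose and 3 fell (1 and 7 adjusted over the list alone; camera Down, adjusted p = 0.00886; adjusted p = 0.401 with an estimated correlation). NDRG1 changed by 0.56 ± 0.13 and PDK1 by -0.92 ± 0.24. This list was not called without scramble replicate 2 (adjusted p = 0.095), without the 3 arrays (adjusted p = 0.0828) or by fry (adjusted p = 0.0991).

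In sphingolipid synthesis, 3 of 25 genes rose and none fell after DEGS1 siRNA (4 and 0 adjusted over the list alone; camera adjusted p = 0.179). UGT8 rose by 0.98 ± 0.13 (adjusted p = 0.0011), as it did after SPTLC123 siRNA, and UGCG, the glucosylceramide synthase, by 0.83 ± 0.20 (adjusted p = 0.0269). The UGCG call was lost with the actin 3'/5' covariate (adjusted p = 0.127). SGPP1, a sphingosine 1-phosphate phosphatase, changed by -1.28 ± 0.09 (adjusted p = 4.09e-05) within the breakdown list, in which 2 rose and 3 fell of 27 (3 and 5 adjusted over the list alone; camera adjusted p = 0.179). The monoglyceride lipase MGLL changed by -1.32 ± 0.10 in the lipid droplet and lipolysis list (2 higher and 2 lower of 19; 2 and 4 adjusted over the list alone). ACSL5 changed by -1.45 ± 0.15 and DGAT2, which makes triglycerides, by -0.98 ± 0.13 in the fatty acid and triglyceride synthesis list (3 higher and 5 lower of 25; 4 and 7 adjusted over the list alone). CDS1 rose by 1.25 ± 0.15 (0.82 without the 3 arrays, adjusted p = 0.0208) among glycerophospholipid synthesis genes (2 higher and 3 lower of 24; 3 and 3 adjusted over the list alone).

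The lists left were not called by camera after DEGS1 siRNA. Fry called 6 lists that camera did not: sphingolipid synthesis (Up, adjusted p = 0.0434), sphingolipid breakdown (Down, adjusted p = 0.0354), and lipid droplets and lipolysis, lipoproteins and cholesterol efflux, the unfolded protein response (each Down, adjusted p = 0.0434) and the reference genes (Down, adjusted p = 0.0441). Without the 3 arrays with weak 5' signal the median change of lipid droplets and lipolysis was -0.016, against -0.106. That of the reference genes was then -0.029, against -0.109. For sphingolipid synthesis and breakdown the medians were 0.059 and -0.066, against 0.070 and -0.056. Lipoproteins and cholesterol efflux had 0 higher and 5 lower of 24 (0 and 6 adjusted over the list alone; camera adjusted p = 0.179), with SOAT1 at -0.87 ± 0.11. With the actin 3'/5' covariate this list was called by camera (Down, adjusted p = 0.0312). Without the 3 arrays with weak 5' signal its median change was -0.18, against -0.07. Over all arrays its adjusted p was 0.401 with an estimated correlation. Cholesterol synthesis and uptake had 3 higher and 0 lower of 19 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0628), with the lanosterol synthase LSS at 0.88 ± 0.17. It was called Up by camera without scramble replicate 2 (adjusted p = 0.00502) and without DEGS1 replicate 3 (adjusted p = 0.0134). Quantile normalization (adjusted p = 0.0103) and the actin 3'/5' covariate (adjusted p = 0.0230) also gave this call. Without the 3 arrays its median change was 0.19, against 0.11. Over all arrays its adjusted p was 0.401 with an estimated correlation. The unfolded protein response had 1 higher and 5 lower of 20 (2 and 9 adjusted over the list alone), with EDEM1 at -1.07 ± 0.12 and PDIA4 at 0.79 ± 0.09. By camera it was called Down without scramble replicate 2 (adjusted p = 0.0248), with array weights (adjusted p = 0.0392) and with the actin 3'/5' covariate (adjusted p = 0.0361). Without the 3 arrays with weak 5' signal its median change shrank to -0.095, against -0.206. Over all arrays its adjusted p was 0.401 with an estimated correlation. LAMP1, a lysosomal membrane protein, changed by -1.03 ± 0.12 in the autophagy and lysosome list (3 higher and 4 lower of 24; 4 and 6 adjusted over the list alone). CCN2 changed by -1.38 ± 0.25 among actin cytoskeleton, adhesion and matrix genes (3 higher and 2 lower of 26; 6 and 3 adjusted over the list alone). The cell cycle list had 2 higher and 0 lower of 31 (4 and 3 adjusted over the list alone), with CCNE1 at 0.83 ± 0.13. The p53 targets and apoptosis list had 1 higher and 3 lower of 20 (1 and 5 adjusted over the list alone), with PMAIP1 at -1.09 ± 0.24. With the mean of a gene's probe sets camera called this list (adjusted p = 0.0414). Inflammation and NF-kappaB had 3 higher and 2 lower of 23 (3 and 2 adjusted over the list alone), with CXCL3 at 0.91 ± 0.18. Insulin signalling and glucose metabolism had 3 higher and 3 lower of 22 (3 and 4 adjusted over the list alone), with IGFBP3 at 1.29 ± 0.16. Interferon response had 0 higher and 2 lower of 25 (0 and 2 adjusted over the list alone). Fatty acid oxidation and PPAR-alpha targets had 1 higher of 24 (0 adjusted over the list alone), and markers of other liver cell types 1 lower of 23 (0 adjusted over the list alone). Among 14 reference genes HPRT1 at -0.51 ± 0.09 and TFRC at -0.46 ± 0.10 were called lower (3 lower adjusted over the list alone).

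Many genes were called against scramble after both siRNAs. SI, LZTFL1 and MET rose in both, and SPX and HCAR3 fell in both; SI changed by 3.13 and 3.07, and MET by 2.01 and 1.81. The 770 genes called in both comparisons comprised 453 higher in both, 280 lower in both and 37 in opposite directions, where independent lists of these sizes would share 49.0, 46.1 and 95.6. Simulated unchanged groups sharing the scramble arrays gave at most 1 gene called in both. They held no changed genes, so hardly any gene could be called in them. Their overlap is therefore no baseline for the 770 genes. Across genes, which are not independent replicates, the fold changes had r = 0.533 and a covariance of 0.0509, against r = 0.50 and a covariance of 0.00882 in the simulated groups, a difference of 0.0421. Part of the excess overlap may come from the shared controls. Without the 3 arrays with weak 5' signal, 170 genes were called in both (113 higher, 48 lower and 9 opposite). Leaving out scramble replicate 2 or 3 gave 454 and 422, and leaving out DEGS1 replicate 2 or 3 gave 458 and 422.

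**Figure D3:**
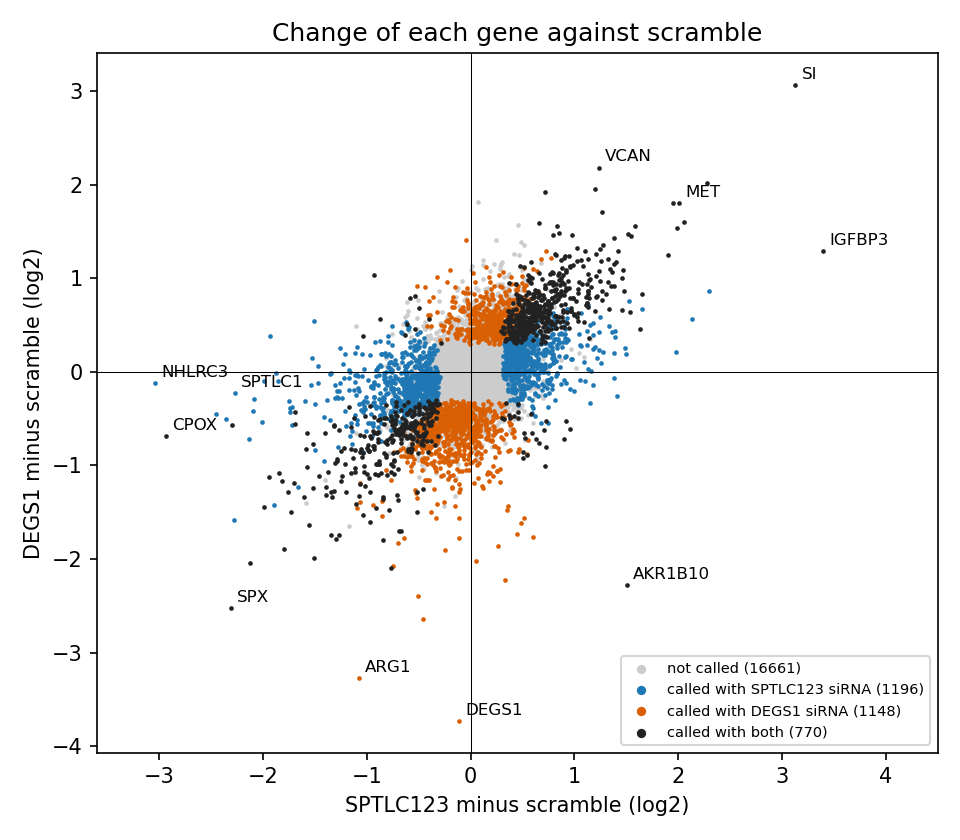
Log2 change of each of the 19775 genes against scramble after SPTLC123 siRNA (horizontal axis) and after DEGS1 siRNA (vertical axis), coloured by the comparisons in which it was called. Most of the 770 genes called in both lie in the quadrants of equal sign, with SI at 3.13 and 3.07, while AKR1B10 lies at 1.50 and -2.28.

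The direct comparison of the siRNAs asks where the responses differ. AKR1B10, an aldo-keto reductase, was lower in DEGS1 than in SPTLC123 siRNA by a log2 difference of -3.78 ± 0.26 (limma with Benjamini-Hochberg adjustment, adjusted p = 1.17e-05). AKR1C1 differed by -2.13 ± 0.23 and AKR1C2 by -2.08 ± 0.18, and GCLC, the catalytic subunit of glutathione synthesis, by -1.06 ± 0.15. In the oxidative stress and NRF2 list 8 of 21 genes were lower and none higher in DEGS1 siRNA (11 and 0 adjusted over the list alone; camera Down, adjusted p = 1.01e-08; adjusted p = 0.289 with an estimated correlation). Of the 22 lists it was the only one called by camera in this comparison; without SPTLC123 replicate 1 the fatty acid and triglyceride synthesis list was also called (Down, adjusted p = 0.0359), as it was with the actin 3'/5' covariate (adjusted p = 0.00574) and with the mean of a gene's probe sets (adjusted p = 0.0471). Over all arrays its adjusted p = 0.678 with an estimated correlation. Fry also called the sphingolipid synthesis list (Up, adjusted p = 0.0249).

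**Figure D4:**
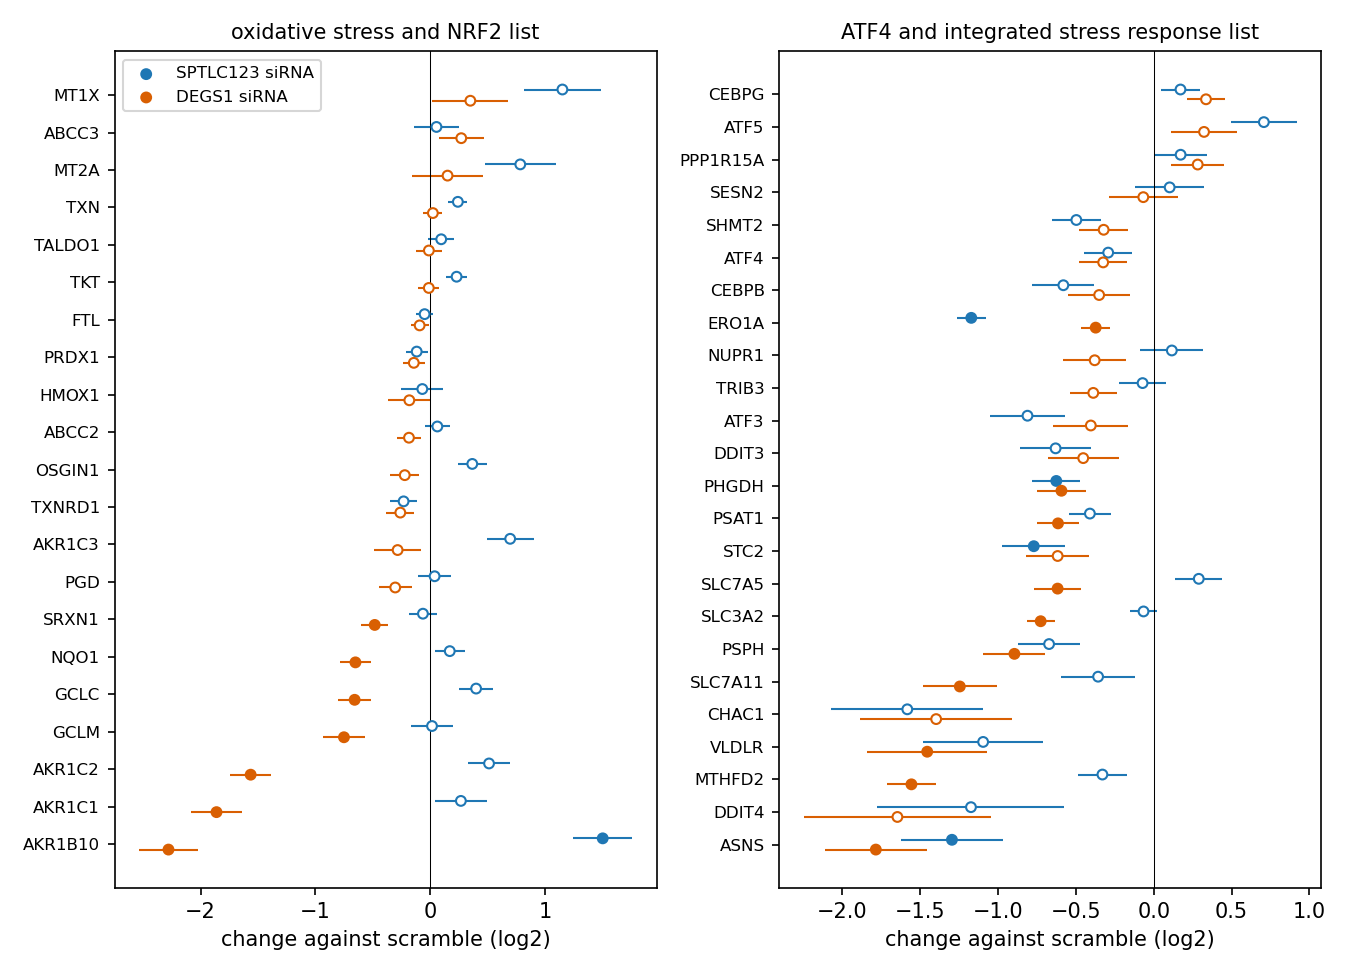
Log2 change against scramble, with its SE, of each measured member of the oxidative stress and NRF2 list and of the ATF4 and integrated stress response list after SPTLC123 and DEGS1 siRNA. Filled points passed an adjusted p of 0.05; AKR1B10 lies at 1.50 after SPTLC123 and at -2.28 after DEGS1 siRNA, and ASNS at -1.30 and -1.79.

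Beyond the targets and AKR1B10, the largest differences between the siRNAs were these. NHLRC3 (2.92 ± 0.19), CPOX (2.25 ± 0.19), WIPF1 (2.05 ± 0.17) and DPYD, which breaks down pyrimidines (2.31 ± 0.13, with both other probe sets of the opposite sign, 1 of them called), were higher in DEGS1 than in SPTLC123 siRNA. USP46 (-2.55 ± 0.20), UGT2B4, a glucuronosyltransferase (-2.37 ± 0.26), and ARG1 (-2.19 ± 0.45) were lower. The SPTLC123 level of NHLRC3 and WIPF1 and the DEGS1 level of AKR1B10 and UGT2B4 lay below the median of all probe sets (4.87). ARG1 lost its call without SPTLC123 replicate 1 (-2.16, adjusted p = 0.0548), SPTLC123 replicate 2 (-1.94, adjusted p = 0.0618) or DEGS1 replicate 3 (-1.82, adjusted p = 0.0573). CERS2 differed by 1.67 ± 0.13, SGPL1 by 0.78 ± 0.09, SOD2 by 1.89 ± 0.15, IGFBP3 by -2.10 ± 0.16, LAMP1 by -1.31 ± 0.12 and APOC3 by 1.00 ± 0.14. In the ATF4 and integrated stress response list 1 gene was higher and 4 were lower of 24 (1 and 4 adjusted over the list alone; camera adjusted p = 0.252): ERO1A differed by 0.80 ± 0.09, MTHFD2 by -1.23 ± 0.16 and SLC7A5 by -0.91 ± 0.15. In all 1713 genes were called, 732 higher and 981 lower in DEGS1 siRNA, of which 224 differed at least 2-fold (389 without DEGS1 replicate 1). Without the 3 arrays with weak 5' signal 281 were called (274 of them among the 1713), 159 higher and 122 lower. Of 73 named and called genes 48 lost the call then, with a median of 90.5% of their difference left. APOC3, ARG1, MTHFD2 and UGT2B4 were among these (adjusted p = 0.149, 0.224, 0.0981 and 0.0552). With median centring 31.7% of the calls were higher, against 42.7%. Leaving out single arrays gave 841 and 1011 without SPTLC123 replicates 1 and 2, and 2911, 868 and 884 without DEGS1 replicates 1, 2 and 3. Within the 3 arrays, which set 2 of DEGS1 against 1 of SPTLC123, limma called 0 genes after adjustment and 3600 at an unadjusted p under 0.05. That fit has 1 residual degree of freedom, so its 0 does not bear on whether the differences hold.

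Over all groups, 3266 of the 19775 genes differed by the F test in limma with Benjamini-Hochberg adjustment. This count was 2126 without SPTLC123 replicate 1, 4970, 2028 and 2054 without DEGS1 replicates 1, 2 and 3, and 1274 without the 3 arrays with weak 5' signal. No list was called in any comparison when the correlation between its members was estimated from these arrays. Other groupings of the same 6 arrays gave up to 5 list calls with the preset correlation.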

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

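Tests chosen after the results they bear on had been seen were the share of the DEGS1 change in DEGS1 replicate 1, the count with that array alone, both covariance tests, the question of untransfected arrays and the list test without the 3 arrays with weak 5' signal. The share of signs among genes not called was also added then. The sign comparison among called genes, the test without aldo-keto reductases and the other groupings were set before their results were seen. Groups of 3 arrays were not tested for outliers.

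Control probe sets, which enter no comparison, lay above the scramble arrays in 3 arrays by more than the scramble range. For actin the 3' minus 5' log2 difference was 1.15 in SPTLC123 replicate 3, 1.31 in DEGS1 replicate 2 and 1.25 in DEGS1 replicate 3, against at most 0.56 in scramble. For GAPDH it was 0.25, 0.40 and 0.40, against at most 0.01. The 18S ribosomal RNA control read 1686 in SPTLC123 replicate 3, against 172 to 677 in scramble.

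The weak 5' signal may account for part of the genes called after DEGS1 siRNA. How large that part is stayed open. DEGS1 replicate 1, an array with ordinary 5' signal, called more genes as the only DEGS1 array than a scramble array did in its place. In the latter fits DEGS1 replicate 1 stood among the controls, which can widen their spread and lower the count. The counts therefore cannot decide whether the weak signal is the whole cause. DEGS1 itself stood at 5.19 in DEGS1 replicate 1, against 8.73 ± 0.13 in scramble. For this gene the fall was thus also seen with ordinary 5' signal. Of the 1918 genes called, 77.5% had a gap between DEGS1 replicates 2 and 3 and replicate 1 of the same sign as the gap of SPTLC123 replicate 3 from its own group. The gaps of SPTLC123 replicates 1 and 2 gave 32.1% and 31.0%. Gaps within a group sum to 0, so these values are not independent of the first. Among the 17857 genes not called the share was 65.1%. Such genes can have smaller gaps with less certain signs, so they are not a matched baseline. Genes called from DEGS1 replicates 2 and 3 against 2 scramble arrays (3538) were followed in DEGS1 replicate 1 against the remaining scramble array. The median share of their change there was 0.234, with quartiles of -0.0659 and 0.554. The same share in SPTLC123 replicate 3, for 697 genes called from its other 2 arrays, was 0.904. These shares are not matched. The 697 genes came from arrays with ordinary 5' signal and were followed in an array with weak signal. An effect of the DEGS1 siRNA remains open for each gene that is called with the weak arrays only.

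A shared response to both siRNAs is a candidate explanation for the 770 genes called in both comparisons (453 higher and 280 lower in both). The covariance of the fold changes, 0.0509, lay above the highest of 100 simulated unchanged groups sharing the controls (0.00927). Without the 3 arrays with weak 5' signal it was 0.0395, above the highest simulated 0.00956. The simulations drew each gene independently, whereas the first principal component of the arrays held 39.5% of the variance. Variation shared across genes can widen the spread of the covariance. The simulations therefore cannot exclude the shared controls or the weak 5' signal as its source. An effect of the scramble siRNA on its own arrays cannot be told apart from a response common to the siRNAs, because 0 untransfected arrays were analysed. Seed matches of the siRNAs were not tested.

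Against scramble, 37 genes were called in opposite directions after SPTLC123 and DEGS1 siRNA. A direct test of the siRNAs adds nothing for them, since the difference is the sum of both changes. AKR1B10, HEPACAM2, CLIC2, ENTPD7 and NKIRAS1 had the largest such changes. Without 1 array HEPACAM2 lost its call in SPTLC123 without scramble replicate 2 (adjusted p = 0.0653) or 3 (0.0538) and in DEGS1 without scramble replicate 3 (0.0502). ENTPD7 lost it in SPTLC123 without scramble replicate 1 (0.115) or 2 (0.144) or SPTLC123 replicate 1 (0.128), 2 (0.112) or 3 (0.0686), and in DEGS1 without DEGS1 replicate 3 (0.0501).

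The oxidative stress and NRF2 list differed between DEGS1 and SPTLC123 siRNA (camera adjusted p = 1.01e-08). Without the 3 arrays with weak 5' signal its camera adjusted p was 4.78e-08 in the same direction. The median log2 difference was then -0.32, against -0.42, with 1 DEGS1 array left. Without AKR1B10 and the 3 AKR1C genes its unadjusted camera p was 1.04e-05 over 17 members, 4 of them called lower. Signal shared between these paralogs does not give the calls of those 4 genes. Both list tests used the preset correlation and were not repeated with an estimated one. For the list as a whole they therefore cannot exclude the weak signal or the shared signal as the source of the difference. A lower NRF2 activity after DEGS1 than after SPTLC123 siRNA may be involved. This hypothesis arose from the same arrays and was not tested, since only transcript levels were measured. It stays open that members correlate within groups, since the camera adjusted p of the whole list was 0.289 with an estimated correlation.

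Other groupings of the arrays bear on chance. Among 100 drawn groupings of the 9 arrays only the real one, counted as 1, gave 3266 genes by the F test, the highest other being 747, so a grouping by chance is an unlikely source of that count. Each pair of groups has 10 splits, too few for a share under 0.05. For SPTLC123 against scramble the real split gave 1966 genes, 271 of them at least 2-fold, and the highest other 1 and 1; for DEGS1 against scramble 1918 and 226, and the highest other 0 and 0. For DEGS1 against SPTLC123 it gave 1713 and 224, and the highest other, which sets the 3 arrays with weak 5' signal against the rest, 1290 and 132. With the actin covariate in the fit of all 9 arrays, the real split gave 2029. For gene lists, 5 were called in SPTLC123 against scramble, with 5 as the highest other and 3 of the 10 splits giving as many; 4 in DEGS1 against scramble, with 5 as the highest other and 3 of the 10 as many; and 1 in DEGS1 against SPTLC123, with 3 as the highest other and 8 of the 10 as many.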

How the results depend on the processing

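The fits with the actin covariate, without the 3 arrays with weak 5' signal, within these arrays and without the aldo-keto reductases were added after seeing the data. Against scramble, the targeted genes kept direction and call in each setting run for those comparisons, which the fit within the 3 arrays is not (SPTLC1 from -2.33 to -2.20, SPTLC2 from -1.12 to -0.95 and DEGS1 from -3.82 to -3.63 when single arrays were left out). Counts are given in the order SPTLC123 against scramble, DEGS1 against scramble, DEGS1 against SPTLC123; those not given lay within 1.5 times the main count, and the cause of the shifts was not tested except where fewer arrays or a stricter threshold make it plain. At an adjusted p of 0.01, 883, 692 and 717 genes were called, 1370 by the F test and 279 in both comparisons against scramble. Array weights, which count arrays with a larger spread less, gave 4263 and 3999 genes for the comparisons with DEGS1, 372 and 376 at least 2-fold. They gave 5917 by the F test, 1254 in both comparisons and r = 0.435 between the fold changes. Every probe set on its own gave 514, 379 and 400 called at least 2-fold, and the mean of a gene's probe sets 152, 128 and 126, with 2 lists in the last comparison. The actin covariate gave 1114 genes and 7 lists for DEGS1 against scramble and 2 lists for DEGS1 against SPTLC123. Without the 3 arrays, DEGS1 against scramble gave 259 genes and 119 at least 2-fold, DEGS1 against SPTLC123 281, the F test 1274 and the overlap 170; within the 3 arrays 0 genes were called (3600 at an unadjusted p under 0.05) in a fit with 1 residual degree of freedom.

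Leaving out single arrays moved the counts to 1178 to 2381, 801 to 3614 and 841 to 2911 genes, to 243 to 321, 175 to 495 and 185 to 389 at least 2-fold, to 2028 to 4970 by the F test and to 422 to 1098 in both comparisons, with r from 0.412 to 0.589; lists called went to 5 to 6, 3 to 5 and 1 to 2. With an estimated correlation 0 lists were called in each comparison, against 5, 4 and 1; fry called 5, 9 and 2. The share of higher calls moved from 53.5% to 65.3% in SPTLC123 against scramble and from 42.7% to 31.7% in DEGS1 against SPTLC123 with median centring, and in the latter to 56.6% without the 3 arrays. In the former it was 46.5% with quantile normalization and 48.7% without scramble replicate 1. In DEGS1 against scramble it was 57.5% without the 3 arrays and 53.1% with the actin covariate, against 48.1%. Keeping every probe set, or leaving out scramble or DEGS1 replicate 2 or 3, gave 50.9% to 53.4%, and a fit on the 2 groups compared left it about even. With the mean of a gene's probe sets 4 named results turned sign and were not called: CHPT1 to 0.0885 and CRLS1 to 0.0415 in DEGS1 against scramble, and CHPT1 to 0.0275 and XBP1 to 0.0570 in DEGS1 against SPTLC123. The 321 named gene results leave out each targeted gene only where its own siRNA is compared with scramble. Of these, 134 lost a call without the 3 arrays, where DEGS1 has 1 array, and 30 with the covariate.

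The replicate numbers were not taken as pairs: deviations from the group means correlated between 0.00579 and 0.213 for scramble with SPTLC123 arrays of the same number, between -0.27 and 0.03 for scramble with DEGS1, between -0.28 and 0.54 for SPTLC123 with DEGS1, and 4 of 9 arrays correlated best with their own number. With the number as a block, 2062, 2168 and 1801 genes were called.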

Other observations

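The gene families here were chosen after their values had been seen, so their p-values are no independent support. The 9 tests (3 families in 3 comparisons) were adjusted together. Metallothioneins, small metal-binding proteins, were higher after SPTLC123 siRNA: 3 of 8 measured members were called, none lower, with MT1M at 1.98 ± 0.28, MT1E at 1.53 ± 0.34 and MT1F at 1.39 ± 0.31 against scramble (camera adjusted p = 3.72e-06; adjusted p = 0.220 with an estimated correlation). After DEGS1 siRNA none of the 8 was called, and the list differed between the siRNAs, with 1 of 8 members called lower, MT1M at -1.76 ± 0.28 (Down in DEGS1, adjusted p = 0.000113; adjusted p = 0.222 with an estimated correlation). Of 4 UGT2B glucuronosyltransferases, which conjugate steroids and bile acids, 2 rose after SPTLC123 siRNA (UGT2B15 by 0.87 ± 0.11 and UGT2B28 by 0.96 ± 0.17) and 2 fell after DEGS1 siRNA (UGT2B4 at -1.76 ± 0.26 and UGT2B28 at -0.61 ± 0.17). The family was called in the former (camera Up, adjusted p = 0.000684; adjusted p = 0.0953 with an estimated correlation) but not in the latter (adjusted p = 0.0740; adjusted p = 0.222 with an estimated correlation). After the removal of the 3 arrays with weak 5' signal UGT2B4 stood at -1.36 (adjusted p = 0.138) and UGT2B28 at -0.38 (adjusted p = 0.388) after DEGS1 siRNA. MT1E then stood at 1.35 after SPTLC123 siRNA (adjusted p = 0.0554). Between the siRNAs 3 of the 4 were lower in DEGS1 (camera adjusted p = 6.02e-05; adjusted p = 0.0872 with an estimated correlation). MT1X and MT2A are also members of the oxidative stress and NRF2 list. Members of both families are close paralogs whose probe sets can share signal.

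Among 31 serpins, a family that holds many protease inhibitors of plasma, 11 were lower and 2 higher after SPTLC123 siRNA (camera adjusted p = 0.0103; adjusted p = 0.220 with an estimated correlation). SERPINC1, antithrombin, changed by -1.61 ± 0.20, SERPINA3 by -1.06 ± 0.19 and SERPINF2, an inhibitor of plasmin, by -0.82 ± 0.10. SERPINA7 and the collagen chaperone SERPINH1, at 0.91 ± 0.10, went the other way. After DEGS1 siRNA 6 were lower and none higher, with SERPINC1 at -1.33 ± 0.20 (camera adjusted p = 0.0496; adjusted p = 0.222 with an estimated correlation). This call ended without the 3 arrays with weak 5' signal (unadjusted p = 0.114, against 0.0331), and SERPINC1 stood at -0.96 (adjusted p = 0.102). The medians over all members were near 0 (-0.05 in both comparisons), so the change lay in part of the family.

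Of the SPTLC1 probe sets not used for the gene, 1 changed by -0.52 in DEGS1 siRNA against scramble (limma over all probe sets with Benjamini-Hochberg adjustment, adjusted p = 0.0225). The other differed by -0.82 (adjusted p = 0.240), with DEGS1 replicate 1 at 9.52 against 9.45 in scramble and replicates 2 and 3, with weak 5' signal, at 8.32 and 8.05, and the probe set used by -0.23 (adjusted p = 0.318 in the same fit).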
